A study of Bos taurus with 8 samples.

How the data were processed

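Whole-genome bisulfite sequencing was used to measure CpG methylation in 8 bovine samples, namely 3 of day 7 trophectoderm (D7 TE), 3 of day 14 trophectoderm (D14 TE) and 2 of bovine trophoblast stem cells (bTSC). Bisulfite turns unmethylated cytosines into bases that are read as T, so the share of C among the reads at a cytosine is its methylation level. Each deposited file held 1 sample, and the samples were grouped by their titles. Nothing in the labels says that the replicates came from separate embryos or cultures, so p-values measure only the spread between these samples, which may be technical. The deposited files of both bTSC samples share a name that is not the group's and may mark a single cell line, in which case the 2 samples would stand for 1 line.

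Per the file headers, each row gave a cytosine of a CpG with its strand, its coverage as a read count, and the percent of those reads showing C and T. The authors deposited coverage as whole read counts without normalization, and the percent values are relative to that coverage. Reads were trimmed with Trim Galore 0.4.3 and processed with Bismark, per the submitters' processing notes; settings and the version of Bismark were not given in the sources used here. The deposited count columns started at 10 reads per cytosine in 7 files and at 3 reads in the file of D7 TE replicate 3, where 45066 of 775318 cytosines had at least 10 reads. Cytosines under 10 reads therefore enter the levels of D7 TE replicate 3 but of no other sample, and the covered cytosines differed strongly between samples. Of the 4077379 cytosines on autosomes and X seen in any file, 75815 were covered in all 8 and 3183005 in only 1.

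The notes name ARS-UCD1.2 as the genome build, but the files do not match it. All 1947 unplaced contigs had names starting with GJ0, which that build does not use. Positions on chromosome X ran to 148823715, which is 9816085 bp beyond the last X gene in the only gene table used here, that of ARS-UCD2.0. Coordinates are therefore given as in the files, from 1, with the build left open, and no gene was assigned to any position. Planned analyses of promoters, gene lists (14 lists), imprinted regions, CpG islands, exons, introns and repeats needed an annotated genome of the files' build and were not run.

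Methylated reads were recovered as coverage times the percent of C, which gave whole reads at 100% of cytosines within the rounding of the 2 decimals. The genome-wide level of a sample is the methylated share of all CpG calls on the 29 autosomes and X. Levels of group means were compared with exact two-sided permutation tests, whose smallest possible p is 0.1 both for 3 against 3 and for 2 against 3 samples. Wilson 95% intervals of the per-sample genome-wide levels reached at most 0.0465 percentage points to each side, and those of the mitochondrial levels 0.200 points. Intervals cover counting error only. At cytosines with 10 reads and an intermediate level, 77.2% to 82.6% of the methylated read counts were even numbers, so the reads at a cytosine are not all independent.

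Calls were summed over non-overlapping 10 kb windows with at least 10 covered cytosines and 20 calls in every sample, which left 1647 windows holding 18.0% to 44.9% of a sample's cytosines. Median calls per window ran from 397 in D7 TE replicate 3 to 4049 in D7 TE replicate 1. Methylated and unmethylated call counts were tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3). The fit had a coverage term per sample and held all 8 samples, and p-values had Benjamini-Hochberg adjustment. A window counted as changed at an adjusted p under 0.05 with a difference of group mean levels of at least 10 percentage points. The common dispersion was 0.129. edgeR gave every window the same quasi-likelihood dispersion (an infinite prior), so windows that vary more than most can receive p-values that are too small. As an alternative, limma 3.58.1 on logit levels with a pseudocount of 1 was run. The edgeR procedure was tested on simulated data at the real coverage for the D14 TE and D7 TE comparison (1647 windows, 200 changed). It made 0 calls with no change and recovered 68% of windows changed by 20 points (4 of 140 calls false). Of those changed by 30 points it recovered 99% (5 of 203 calls false). Simulated windows were drawn independently with the same spread between samples and no shift of a whole library. The real TE libraries ran from 20.3% to 34.7% as wholes, so these rates need not hold for them.

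The groups, tests, thresholds, the 10 kb windows and most alternatives were chosen before the data were examined. Because gene symbols could not be used, named windows follow the part of the naming rule that covers windows: the 3 with the largest rise and the 3 with the largest fall among the called windows of each comparison. Classes of local CpG density (distinct covered CpGs within 50 bp on each side), the removal of each library's median logit level, windows of 100 kb and 1 Mb (at least 50 cytosines), and shares of cytosines per chromosome (cytosines with at most 20 reads) were chosen after seeing the data. Levels of 1 Mb windows were means of per-cytosine percentages at cytosines with at most 50 reads, and levels of the other windows were shares of calls. Pairwise Pearson correlations, root mean square differences and principal components were computed across windows, which are not independent replicates. Alternatives included other call minimums, limma, the compared groups alone, the replicate number as a block, a larger minimum difference, thinned or halved calls, other window sizes, other sets of cytosines or chromosomes, and each sample left out in turn. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the remaining steps.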

Results

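Genome-wide CpG methylation was measured by whole-genome bisulfite sequencing in bovine trophectoderm (TE), the outer cell layer of the blastocyst that forms the fetal part of the placenta, at day 7 and day 14, and in cultured bovine trophoblast stem cells (bTSC). There were 3 samples of D7 TE, 3 of D14 TE and 2 of bTSC. The files held 824253, 1076702 and 864362 covered cytosines for D14 TE replicates 1 to 3, 909810, 730269 and 775318 for D7 TE, and 468931 and 726768 for bTSC. CpG calls numbered between 4208838 in D7 TE replicate 3 and 22128200 in D14 TE replicate 2. The file of D7 TE replicate 3 started at 3 reads per cytosine, with a median of 4, and the other 7 files started at 10 reads, with a median of 12.

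The first comparison asked how TE methylation differed between day 7 and day 14. Genome-wide methylation was 28.4% ± 5.77 (SD, n = 3) in D7 TE and 25.6% ± 6.39 (SD, n = 3) in D14 TE, and these levels overlapped. A few regions stood apart: of 1647 windows of 10 kb, 7 were higher and 1 was lower in D14 TE. The window at chromosome 19, 56620001 to 56630000, stood at 73.9% ± 1.26 in D14 TE and 17.8% ± 8.26 in D7 TE (n = 3 each). On chromosome 14, the windows 2190001 to 2200000 and 2220001 to 2230000 stood at 71.6% ± 2.03 and 64.1% ± 11 in D14 TE, against 24.8% ± 12.6 and 17.7% ± 3.67 in D7 TE. Calls per sample ran from 48 to 927 in the chromosome 19 window, and from 63 to 665 and 78 to 1282 in the chromosome 14 windows. The window on chromosome 28, 1890001 to 1900000, which held 12865 to 88023 calls in a sample, went the other way, with 22.8% ± 10.7 in D14 TE and 53.7% ± 8.28 in D7 TE.

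The genome-wide difference of D14 TE minus D7 TE was -2.78 percentage points, within the spread between replicates (exact permutation test, two-sided p = 0.6; the smallest possible p was 0.1), and it was 0.385 points without D7 TE replicate 3. Apparent methylation of the mitochondrial genome, a background measured the same way, was 10.5% ± 3.66 (SD, n = 3) in D7 TE and 4.45% ± 0.250 (SD, n = 3) in D14 TE. It differed by strand, with 27.7% forward and 6.31% reverse in D7 TE and 11.9% and 3.44% in D14 TE. The cause of the strand gap was not tested, so this background is no plain measure of conversion. The chromosome 19 window rose by 56.1 points and was higher in 3 of 3 D14 TE samples than in any D7 TE sample (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.00149). In the same edgeR test the chromosome 14 windows rose by 46.8 points (adjusted p = 0.0364) and 46.4 points (adjusted p = 0.0190), each in 3 of 3 samples. The chromosome 28 window fell by 30.9 points (edgeR adjusted p = 0.00117), in 3 of 3 samples. The chromosome 14 calls were lost in 6 of 16 alternatives (2190001) and 2 of 16 (2220001), both of them without D14 TE replicate 1 (adjusted p = 0.178 and 0.0909 in edgeR) or replicate 3 (0.326 and 0.228), and the first also without D7 TE replicate 1 (0.159) or either bTSC library (0.0557 and 0.0652), though the rise stayed at 41.6 points or more. The chromosome 28 call was lost with limma (adjusted p = 0.0745) and, with a difference of -29.7 points, without cytosines above 50 reads (edgeR adjusted p = 0.130). With each library's median removed, limma called 3 windows higher and 0 lower (364 at an unadjusted p under 0.05), with 1 higher without D14 TE or D7 TE replicate 3, and 0 without D14 TE replicate 1 (316 at that p) or D7 TE replicate 2 (349). The 7 and 1 windows moved to 14 higher and 7 lower with limma alone, 17 and 514 without D14 TE replicate 2, 4 and 1 without D14 TE replicate 3, 7 and 2 without D7 TE replicate 1, 11 and 3 without D7 TE replicate 2, and 12 and 4 without D7 TE replicate 3.

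**Figure D1:**
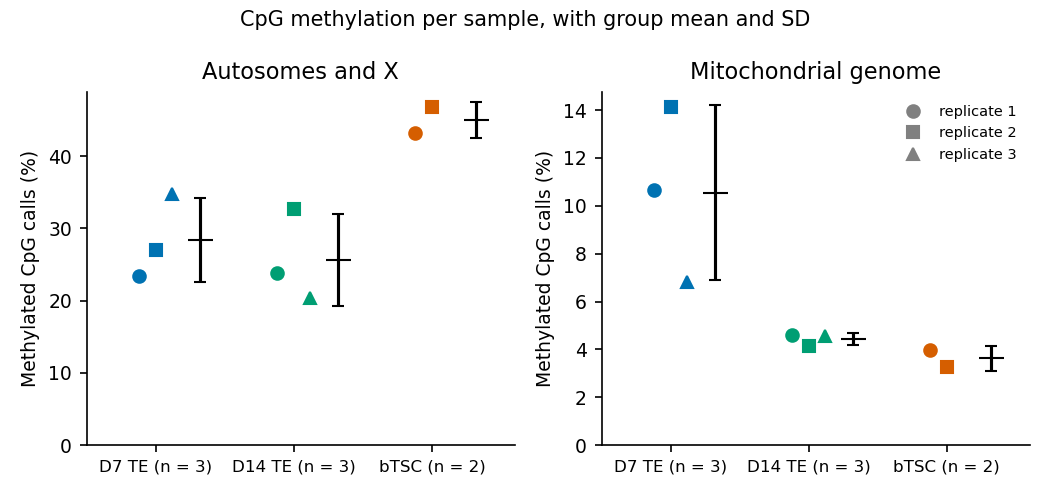
Methylated share of CpG calls in percent (vertical axes) for each sample on autosomes and X (left) and on the mitochondrial genome (right), by group; circles, squares and triangles are replicates 1, 2 and 3, and black bars give the group mean ± SD. Both bTSC samples (43.3% and 46.7%) lay above all 6 TE samples on autosomes and X, while mitochondrial levels were highest in D7 TE.

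The second comparison set bTSC against D14 TE. Genome-wide methylation was 45% ± 2.46 (SD, n = 2) in bTSC, 19.4 percentage points above D14 TE. The levels of 43.3% and 46.7% both lay above the highest D14 TE sample at 32.7%. These levels are weighted by calls. As means of per-cytosine percentages they were 53.3% in bTSC and 29.5% in D14 TE, 23.7 points apart. Per-cytosine levels in bTSC replicates 1 and 2 were 58.4% and 60.4% at 10 to 12 reads, and 35.7% and 36.2% above 200 reads. Cytosines above 200 reads held 14.7% to 20.3% of the calls on autosomes and X in 7 files and 2.05% in D7 TE replicate 3. Among cytosines with at least 10 reads, those with no methylated read made up 11.8% ± 0.902 in bTSC and 32.0% ± 6.71 in D14 TE, and those above 80% methylation made up 29.3% ± 4.20 and 9.66% ± 1.44 (SD, n = 2 and 3). The gain was spread over the genome: 955 of 1647 windows, on all 30 chromosomes, were higher in bTSC by a median of 23.8 points, and 4 were lower. At chromosome 27, 5100001 to 5110000, methylation was 83.7% ± 2.22 in bTSC and 12.1% ± 10.8 in D14 TE. At chromosome 6 it was 81.7% ± 2.03 and 12.7% ± 5.83 in the window 6560001 to 6570000 and 79.6% ± 1.2 and 10.9% ± 9.45 in the window 5320001 to 5330000. Calls per sample ran from 111 to 962 in the chromosome 27 window, and from 190 to 2772 and 64 to 1023 in the chromosome 6 windows.

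The genome-wide difference between bTSC and D14 TE had an exact two-sided permutation p of 0.1, the smallest possible. By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, the chromosome 27 window was 71.6 points higher (adjusted p = 1.48e-08) and the chromosome 6 windows 69.0 points (adjusted p = 1.85e-09) and 68.7 points higher (adjusted p = 2.08e-08), in 2 of 2 bTSC samples each. Among the lower windows, chromosome 29, 49200001 to 49210000, fell by 42.5 points to 15.9% ± 1.03 from 58.5% ± 11.7 in D14 TE (edgeR adjusted p = 0.0124), in 2 of 2 bTSC samples. The windows at chromosome 14, 76350001 to 76360000, and chromosome 28, 29780001 to 29790000, fell by 19.9 points (17% ± 0.697 against 36.9% ± 14.5, edgeR adjusted p = 0.0334) and by 17.1 points (10.7% ± 0.359 against 27.9% ± 10.5, adjusted p = 0.0393) in 2 of 2 bTSC samples. Calls per sample ran from 56 to 372 in the chromosome 29 window, 3487 to 37537 on chromosome 14 and 141 to 2317 on chromosome 28. The fourth, at chromosome 22, 42420001 to 42430000, was named after its values were seen and fell by 13.5 points (11.8% ± 0.251 against 25.3% ± 6.29, edgeR adjusted p = 0.0484) in 2 of 2 bTSC samples. With each library's median removed, so that only changes relative to the genome-wide shift remained, limma called 69 windows higher and 137 lower, 45 higher without D14 TE replicate 2, and 1 and 2 higher with 0 lower without bTSC replicate 1 and 2 (292 and 294 windows at an unadjusted p under 0.05). The 955 higher windows became 141 and 146 without bTSC replicate 1 and 2, 216 without D14 TE replicate 1, 380 without D14 TE replicate 3 and 594 with these groups alone in the edgeR fit. The 4 lower windows became 1 without D14 TE replicate 1 or D7 TE replicate 2, and 1 with limma. The calls on chromosomes 14, 28 and 29 were lost in 9 of 18, 11 of 19 and 3 of 16 alternatives. These losses include the fits without either bTSC library, which leave a single bTSC sample. Without bTSC replicate 1 and 2 the differences were -19.4 and -20.4 points on chromosome 14, -16.9 and -17.4 on chromosome 28, and -41.8 and -43.3 on chromosome 29. The chromosome 14 window differed by only -8.36 points (edgeR adjusted p = 0.473) without cytosines above 50 reads.

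**Figure D2:**
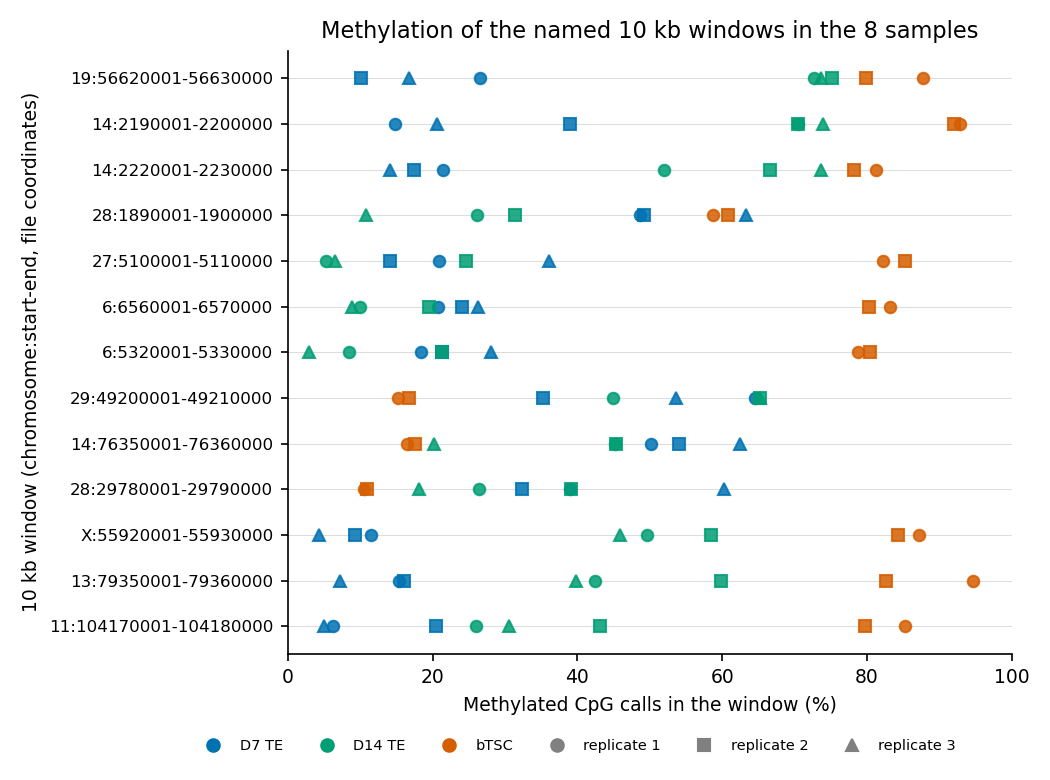
Methylated share of CpG calls in percent (horizontal axis) in each of the 13 named windows of 10 kb (vertical axis, chromosome, start and end as in the files), with a point per sample, colours for the 3 groups and shapes for replicates. At chromosome 19, 56620001 to 56630000, D14 TE (73.9%) lay near bTSC and far from D7 TE (17.8%), while at chromosome 27, 5100001 to 5110000, D14 TE (12.1%) lay near D7 TE and far from bTSC (83.7%).

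The third comparison set bTSC against D7 TE. The difference was 16.6 percentage points, and both bTSC samples lay above the highest D7 TE sample at 34.7%. As means of per-cytosine percentages the levels were 53.3% in bTSC and 30.3% in D7 TE, 23.0 points apart. Of 1647 windows, 543 were higher and 34 lower in bTSC. At chromosome X, 55920001 to 55930000, methylation was 85.7% ± 2.02 (SD, n = 2) in bTSC and 8.35% ± 3.71 (SD, n = 3) in D7 TE, and D14 TE lay between them at 51.3% ± 6.47. The windows at chromosome 13, 79350001 to 79360000, and chromosome 11, 104170001 to 104180000, stood at 88.6% ± 8.42 and 82.5% ± 3.91 in bTSC, against 12.9% ± 4.97 and 10.6% ± 8.59 in D7 TE. Calls per sample ran from 47 to 1605 in the chromosome X window, 56 to 514 on chromosome 13 and 40 to 654 on chromosome 11.

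The genome-wide difference between bTSC and D7 TE had an exact two-sided permutation p of 0.1, the smallest possible, and was 10.8 points at the cytosines covered in all 8 samples. By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, the windows on chromosomes X, 13 and 11 were higher in 2 of 2 bTSC samples, by 77.4 points (adjusted p = 1.49e-09), 75.8 points (adjusted p = 1.43e-06) and 71.9 points (adjusted p = 5.23e-06). The windows on chromosomes 14, 29 and 28 that were low in bTSC in the second comparison, which shares its bTSC libraries with this one, stood at 55.5% ± 6.24, 51.1% ± 14.8 and 43.9% ± 14.6 in D7 TE. In the edgeR test they fell by 38.5 points (adjusted p = 0.000220), 35.2 points (adjusted p = 0.0371) and 33.2 points (adjusted p = 0.00160) in 2 of 2 bTSC samples. The chromosome 29 call was lost in 7 of 16 alternatives, and the chromosome 28 call in 2 of 18, without bTSC replicate 1 or 2 (edgeR adjusted p = 0.0680 and 0.0629). With each library's median removed, limma called 311 windows higher and 188 lower, and 101 and 97 or 88 and 96 without bTSC replicate 1 or 2. The 543 higher windows became 182 and 174 without bTSC replicate 1 and 2, 357 without D7 TE replicate 1, 921 without D14 TE replicate 2 and 881 with these groups alone in the edgeR fit. The 34 lower windows became 1 without either bTSC library, 17, 12 and 15 without D7 TE replicates 1 to 3, and 22, 94 and 53 without D14 TE replicates 1 to 3.

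The levels were then set out by local CpG density, counted over CpGs covered in any of the 8 files. An isolated CpG here may thus have neighbours in the genome that no file covered. In all 3 groups, levels were lower at the densest CpGs than at isolated ones. Cytosines with over 15 distinct CpGs within 50 bp on each side stood at 13.2% ± 3.23 in D14 TE and 18.5% ± 2.94 in D7 TE (n = 3 each). In bTSC that class stood at 45.8% ± 0.300 (SD, n = 2). Isolated CpGs stood at 57.6% ± 1.43 in bTSC, 26.6% ± 4.09 in D14 TE and 30.8% ± 5.59 in D7 TE. On chromosome X the levels were 43.3% ± 1.12 in bTSC, 23.3% ± 7.58 in D14 TE and 28.1% ± 6.49 in D7 TE, against 45%, 25.7% and 28.4% on the autosomes.

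In the densest class the 2 bTSC samples lay 32.6 points above D14 TE and 27.3 points above D7 TE, each above 3 of 3 samples (exact two-sided permutation p = 0.1 each, the smallest possible; Benjamini-Hochberg p = 0.163 and 0.130 over 13 contexts). That class rested on 2761 to 6580 cytosines per sample. As a mean of per-cytosine percentages it stood at 33.1% in bTSC, 8.67% in D14 TE and 12.4% in D7 TE. In the third of windows with the fewest CpGs, D14 TE (23.8% ± 4.48) lay below D7 TE (35.1% ± 6.02) with no overlap of 3 against 3 samples (exact two-sided permutation p = 0.1, the smallest possible; Benjamini-Hochberg p = 0.758).

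**Figure D3:**
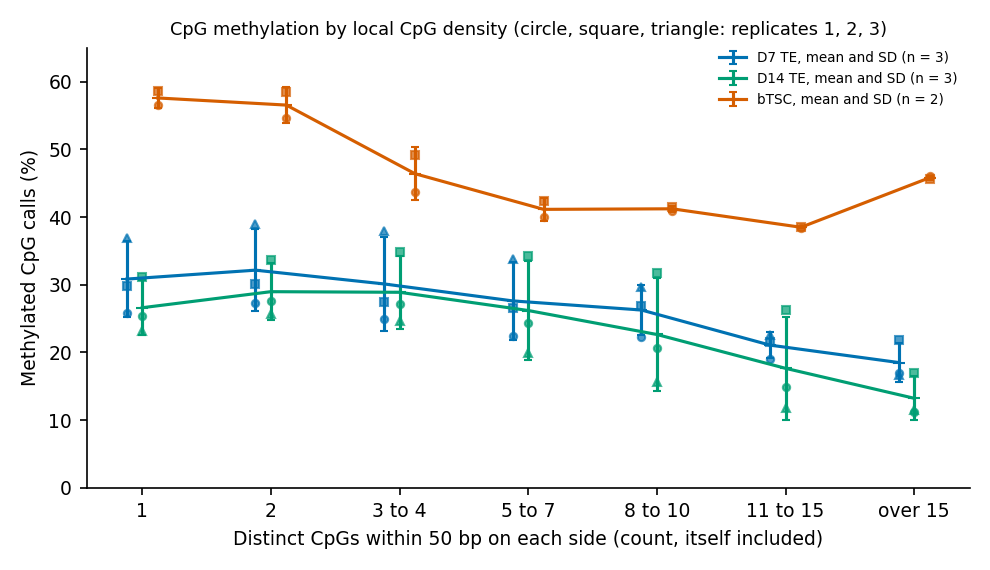
Methylated share of CpG calls in percent (vertical axis) by the count of distinct covered CpGs within 50 bp on each side of a cytosine (horizontal axis); lines with bars give the group mean ± SD (n = 3, 3 and 2) and small points the samples. Isolated CpGs and the densest class stood at 26.6% and 13.2% in D14 TE, 30.8% and 18.5% in D7 TE, and 57.6% and 45.8% in bTSC.

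The window levels were compared between all samples to place bTSC relative to both TE stages. Across the 1647 windows, bTSC correlated with D14 TE at a mean Pearson r of 0.707 (0.664 to 0.747 over 6 pairs of samples) and with D7 TE at 0.459 (0.423 to 0.509 over 6 pairs). Samples of the same group correlated at 0.930 in bTSC, 0.883 in D14 TE and 0.681 in D7 TE. In absolute level bTSC lay about equally far from both stages, with a root mean square difference of 25.3 points from D14 TE (18.9 to 29.2) and 26.5 from D7 TE (25 to 28.6). The first principal component held 65% of the variance and parted bTSC from all TE samples. The second held 16.1% and parted D7 TE from D14 TE. These are descriptions across windows, without a test. The order of the differences turned in windows of 1 Mb, with 30.8 points from D14 TE and 29.6 from D7 TE.

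**Figure D4:**
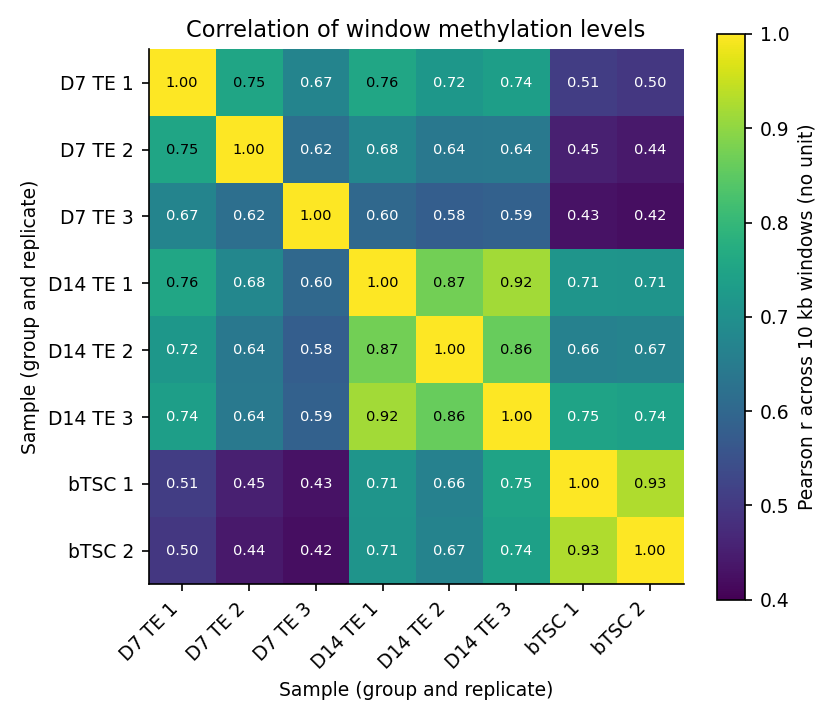
Pearson r across 1647 windows of 10 kb between the methylation levels of each pair of samples (both axes list the samples by group and replicate; colour and printed value give r, no unit). Pairs of bTSC with D14 TE ran from 0.664 to 0.747 and pairs of bTSC with D7 TE from 0.423 to 0.509.

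The bTSC libraries also stood apart in where their covered cytosines lay. Chromosome 11 took 10.5% of the cytosines with at most 20 reads in bTSC and 4.82% ± 0.183 (SD, n = 6) in TE. Relative to the TE mean, and with each library's median over chromosomes set to 1, the share was 2.51 on chromosome 11, 1.94 on chromosome 20, 1.90 on chromosome 14, 1.86 on chromosome 29 and 1.46 on chromosome 13, where no TE sample exceeded 1.16. It was 0.607 on chromosome 4 and 0.693 on chromosome X, but not evenly along them. In bins of 10 Mb the ratio ran from 0.154 to 1.52 on chromosome 4 and from 0.218 to 1.27 on X. Without chromosomes 4, 11, 13, 14, 20, 29 and X, bTSC were 18.1 points above D14 TE and 15.9 points above D7 TE (exact two-sided permutation p = 0.1 and 0.2; the smallest possible p was 0.1).

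**Figure D5:**
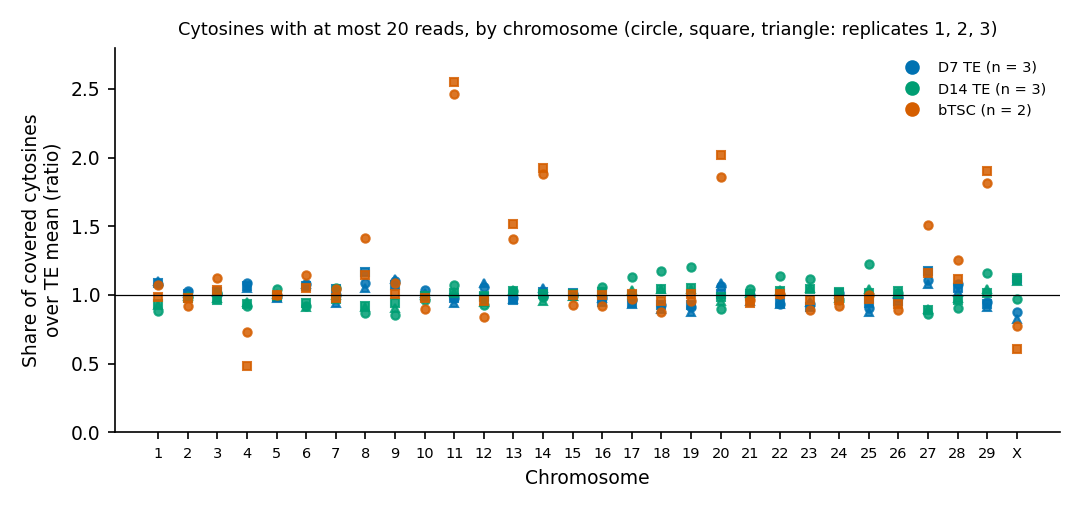
Share of a sample's covered cytosines (those with at most 20 reads) on each chromosome, as a ratio to the mean of the 6 TE samples with each sample's median set to 1 (vertical axis), by chromosome (horizontal axis), with a point per sample. Both bTSC samples lay above all TE samples on chromosomes 11, 13, 14, 20 and 29, with a mean of 2.51 on chromosome 11, and below all TE samples on chromosomes 4 and X.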

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

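The tests in this part were chosen after the result each one measures had been seen, except the test for more copies of a chromosome. No outlier test was made, since the groups hold 2 or 3 samples.

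Both bTSC libraries held a larger share of their covered cytosines than any TE library on chromosomes 11 (2.51 times the TE mean, with each library's median over chromosomes set to 1), 20 (1.94), 14 (1.90), 29 (1.86) and 13 (1.46). The margin was wider than the whole TE range, a rule set after the ratios were seen. The shares of chromosomes 4 (0.607) and X (0.693) were lower, though not evenly along either. A bias towards CpG-dense sequence is argued against by the 5 other chromosomes with the most covered CpGs per Mb, whose median ratio was 0.982. A few amplified regions are argued against by ratios above 1.3 in 43 of the 43 bins of 10 Mb (100%). More copies of these chromosomes per cell is a candidate explanation that cannot be told apart from a technical cause with these data: the ratio at 14 to 16 reads over that at 10 to 11 reads had a median of 1.04 and was above 1 on 5 of 5 chromosomes in bTSC replicate 2 but on 1 of 5 in replicate 1. The small excess at deeper cytosines, with share ratios of 0.977 to 1.25 at 21 to 50 reads and read ratios of 0.853 to 1.13 at a fixed set of deep cytosines, goes against more copies, which stays open because the bTSC libraries differed in the ratio by reads and because deep cytosines may lie in repeated sequence, a point not tested.

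The higher genome-wide methylation of bTSC was weighed against technical causes. Incomplete bisulfite conversion as the whole cause would raise the apparent mitochondrial level by about as much, but it was 3.63% in bTSC and 4.45% in D14 TE, with means of 10.6% and 11.9% on the forward strand, where the samples overlapped, and 2.45% and 3.44% on the reverse strand. The shifted chromosomes are not the whole source, since 18.1 points over D14 TE remained without them (exact two-sided permutation p = 0.1), nor is the choice of cytosines, since 16.9 points over D14 TE (p = 0.2) and 10.8 over D7 TE (p = 0.1) remained at those covered in all 8 samples. These shared cytosines had lower levels in all groups (36.0% in bTSC, 19.1% in D14 TE and 25.2% in D7 TE). The smaller figure over D7 TE, against 16.6 points, therefore cannot tell a part due to that choice from a real difference between sets of cytosines. A biological difference between cultured cells and embryonic tissue may account for what remained, as a hypothesis found and tested on the same 2 bTSC libraries.

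On unplaced contigs, which the comparisons leave out, the bTSC mean was 48.3% of calls, above the highest TE sample (D14 TE replicate 2) at 46.2%, but as a mean of per-cytosine percentages it was 49.8%, below that sample at 50.8%. The apparent mitochondrial level, also outside the comparisons, ran from 3.27% in bTSC replicate 2 to 14.1% in D7 TE replicate 2.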

How the results depend on the processing

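Added after seeing the data were the 10-read and 50-read limits per cytosine, the settings without 7 chromosomes, with halved calls, with medians removed, with windows of 100 kb and 1 Mb, windows in cytosines covered in all 8 samples or chosen in the 7 deeper samples, and all alternatives for density classes. Where no reason is given, the cause was not tested. Genome-wide, the bTSC mean stayed above both TE means in every alternative. The exact two-sided permutation p rose from 0.1, the smallest possible, to 0.2 over D14 TE at cytosines covered in all 8 samples and over D7 TE without 7 chromosomes. Leaving out 1 sample gave 16.7 to 22.9 points over D14 TE and 14.1 to 19.8 over D7 TE. D14 TE minus D7 TE ran from -6.33 to 0.385, and turned only without D7 TE replicate 3, the shallow file. The densest and the isolated CpG classes kept their direction in every alternative.

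Counts of 10 kb windows are given as higher and lower. For D14 TE minus D7 TE (7 and 1), they were 14 and 7 with limma, 2 and 0 in 25 kb windows and 1 and 2 in 100 kb windows. They were 1 and 1 without 7 chromosomes and at cytosines covered in all 8 samples, and 20 and 4 in windows chosen in the 7 deeper samples. With limma after medians were removed, they were 3 and 0, or 4 and 5 in 100 kb windows. Lower windows numbered 2 with thinned calls, 3 without cytosines above 50 reads and 2 with halved calls. Leaving out 1 sample gave 4 to 17 higher and 1 to 514 lower, the latter without D14 TE replicate 2. With medians removed, 10 kb windows numbered 1 without either replicate 3 and 0 without D14 TE replicate 1 or D7 TE replicate 2 (limma, 316 and 349 at an unadjusted p under 0.05), and 100 kb windows 0 without any 1 of the 6 TE samples (limma, 992 to 1408 at that p).

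For bTSC minus D14 TE (955 and 4), they were 594 and 1 with the compared groups alone, 1919 and 3 in 25 kb windows and 4812 and 5 in 100 kb windows. They were 620 and 2 without 7 chromosomes and 577 and 4 at cytosines covered in all 8 samples. With limma after medians were removed, they were 69 and 137, or 46 and 194 in 100 kb windows. A single window was lower (1) with limma, with at least 20 points and without cytosines above 50 reads. The 46 and 194 became 8 and 82, 12 and 38, and 12 and 124 without D14 TE replicates 1 to 3, and 3 and 17 without bTSC replicate 1. Leaving out 1 sample gave 141 to 1287 higher and 0 to 3 lower with medians kept. For bTSC minus D7 TE (543 and 34), they were 881 and 94 with the compared groups alone, 1741 and 33 in 25 kb windows and 4448 and 67 in 100 kb windows. They were 326 and 17 without 7 chromosomes, 237 and 27 at cytosines covered in all 8 samples, and 700 and 17 in windows chosen in the 7 deeper samples. With limma after medians were removed, they were 311 and 188, or 162 and 479 in 100 kb windows. Lower windows numbered 19 with limma, 22 with at least 20 points and 20 without cytosines above 50 reads. The 162 and 479 became 52 and 255 without bTSC replicate 1. Leaving out 1 sample gave 174 to 921 higher and 1 to 94 lower with medians kept. A lone bTSC sample was assumed to vary like the other groups. More windows were tested at 25 kb (3148) and 100 kb (6170), and fewer without 7 chromosomes (1129) and at shared cytosines (1137).

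The named windows kept their direction in the 140 alternative values that recomputed their levels, and passed the threshold in 230 of the 272 that could change the call. Leaving out 1 sample could not turn a direction, since the samples of the compared groups did not overlap in any named window. These windows were also picked for their large differences in the same data. The gap in correlation with bTSC, D14 TE minus D7 TE, was 0.341 in 1 Mb windows and 0.229 to 0.270 with 1 sample left out. The gap in root mean square difference reversed to 1.2 in 1 Mb windows and ran from -3.18 to 1.73 with 1 sample left out. Levels in 1 Mb windows were measured in another way, so more than the window size differed there.

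Replicate numbers gave no clear sign of pairing. For this, deviations from the group mean across 10 kb windows, with library medians removed, were correlated between samples of different groups. Same-numbered samples had small positive correlations of 0.00496 to 0.0774, and other pairs ran from -0.0990 to 0.0798. D14 TE replicate 1 correlated more with D7 TE replicate 2 (0.0155) than with D7 TE replicate 1 (0.00496). The deviations of the 2 bTSC samples mirror each other by construction. Such values cannot show that the samples were unpaired. With the number as a replicate block, the genome-wide differences were -2.78, 16.7 and 19.8 points (exact paired permutation p = 1, 0.5 and 0.5, where 0.5 is the smallest possible with 2 pairs and says nothing about stability), and the windows 8 and 1 for D14 TE minus D7 TE, 481 and 1 for bTSC minus D14 TE, and 481 and 27 for bTSC minus D7 TE. The minimum of 10 calls removed no window, so it tested nothing. The alternatives set out for promoters, gene lists, imprinted regions and named genes were not run, for lack of an annotated genome of the files' build. Windows held the fewest calls in D7 TE replicate 3, with a median of 397.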

Other observations

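Every test in this part was chosen after the results were seen, and so were the 100 kb and 1 Mb windows. At the 7 windows of 10 kb that were higher in D14 TE than in D7 TE, bTSC, which did not enter that difference, had a mean above that of D7 TE in 7 and above that of D14 TE in 6, from 24.7% to 92.5%. Over all 1647 windows the bTSC mean was above that of D7 TE in 86.9% and above that of D14 TE in 90.7%, so these counts do not set the 7 windows apart. At chromosome 28, 1890001 to 1900000, the 1 window lower in D14 TE (22.8%), bTSC stood at 59.8% and D7 TE at 53.7%.

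With library medians removed, limma called 4 windows of 100 kb higher and 5 lower in D14 TE than in D7 TE (1518 at an unadjusted p under 0.05), but 0 whichever TE sample was left out (992 to 1408). At chromosome 20, 55700001 to 55800000, levels were 38.5% ± 7.57 in D7 TE, 81.0% ± 4.78 in D14 TE and 92.1% ± 0.815 in bTSC. At chromosome 9, 81400001 to 81500000, they were 14.3% ± 1.86, 51% ± 4.79 and 61.0% ± 6.15. At chromosome 25, 8600001 to 8700000, D14 TE was low, with 44.8% ± 9.90, 4.61% ± 3.06 and 37.4% ± 9.41. Levels also varied more along the genome in bTSC, with an SD across 1 Mb windows of 13.3 ± 0.623 points (n = 2) against 8.52 ± 0.729 in D14 TE and 6.22 ± 0.602 in D7 TE (n = 3 each).

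The higher correlation of bTSC with D14 TE than with D7 TE could come from noisier D7 TE libraries. With the correlation within groups divided out, it was 0.780 for D14 TE and 0.577 for D7 TE in 10 kb windows and 0.762 and 0.649 in 25 kb windows, where the gap was smallest. Over windows of 10 kb, 25 kb, 100 kb and 1 Mb, the gap was at least 0.0857 whichever of the 6 TE libraries was left out and 0.135 without the shallow file of D7 TE replicate 3, both against noise as the whole cause. That cultured bTSC have a pattern along the genome nearer to the later stage may be stated as a hypothesis, with different cell types in the tissue samples not tested.

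The 6 TE samples can be split into 10 pairs of groups of 3, too few for a share under 0.05. In 10 kb windows the real groups gave 8 calls, and 2 of the 10 splits, the real one included, gave at least as many. The other, with 695, set D14 TE replicates 1 and 3 with D7 TE replicate 1 against the rest. These are the TE samples with the lowest genome-wide levels (23.8%, 20.3% and 23.5%), so this split points to a structure of the samples that follows the level of the whole library. With medians removed the real groups gave 3 calls in 10 kb windows (highest other 1) and 9 in 100 kb windows (highest other 0), each the most of the splits (1 of 10).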
